A study of Caenorhabditis elegans with 4 samples.

How the data were processed

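Worms were grown at 20 degrees Celsius and fixed with 2% formaldehyde, and chromatin was precipitated with a goat antibody against GFP, per the labels' protocols. The 4 samples fell into an anti-GFP ChIP group and an input group, each with replicates 1 and 2, taken from the sample titles. Peak lists were used for the 2 ChIP replicates and for a combined list. Input libraries were not analysed here, so no background was measured in them, and how the input entered the peak calls is not given in the sources used here.

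Peaks were called with PeakSeq on the WormBase WS180 build, per the file headers and the caller column. Each peak carries a position and a q-value, which the authors deposited as a score column and again as an attribute, with the same number in both. The aligner, read filters, caller settings, q threshold and the way the replicates were combined are not given in the sources used here. The highest q in the lists was 0.000416 in replicate 1, 0.000294 in replicate 2 and 0.000486 in the combined list. No line had a q of 0. The lists give no read counts or summits, so depth is unknown, and the precision of each share is that of its number of peaks. Intervals are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only. Coordinates are 1-based as in the files. A stricter or looser caller threshold and a deeper library would both change the number and width of peaks.

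The −log10 q of each peak was computed from the decimal text of its q-value, since the lowest value equals the smallest number that double precision holds (−log10 of 323.3). It was used to rank or filter peaks within a list, to compare peaks at the same position, and to fit a line of the combined value on the sum of both replicates' values. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

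Peaks of the replicates were compared by an overlap of at least 1 bp, with 10000 circular shifts of replicate 2 within each chromosome as the chance level. Each replicate 1 peak was paired with its overlapping replicate 2 peak of lowest q for the rank correlation. The length of each chromosome was taken as the span from the first to the last base of any peak in the 3 lists, because the assembly length of WS180 was not used here; the design had foreseen the assembly length. Chromosome counts were tested by exact binomial tests against the share of the span, with Benjamini-Hochberg adjustment over 6 chromosomes, and by permutation of 1 Mb windows. Clustering was compared with 1000 random placements of the same peaks that kept gaps of at least 200 bp. The overlap and chromosome steps were tested on simulated peaks. Of 4008 simulated peaks, 59.8% were copied to a second list with shifts of up to 50 bp and 59.5% were recovered as shared. Of 20 pairs of unrelated lists, each drawn as 1000 peaks and tested with 200 shifts, 0 passed at 0.05. A chromosome III ratio of 1.33 was recovered as 1.30. All simulated peaks were placed independently, whereas the real peaks were clustered, so these checks do not cover the effect of clustering on the tests.

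The comparisons, gene lists, naming rule and first set of alternatives were fixed before the data were examined. The alternatives were a 50% reciprocal overlap, centres within 100 bp, the 50% of peaks with the lowest q, lists of equal length, peaks with support in both replicates, and each replicate alone. The naming rule took ceh-38, ceh-28 and unc-119 (the strain's rescue marker), the genes at the 15 combined peaks of lowest q that overlapped both replicates, and members of each gene list with a promoter peak. Only the positions of those 15 peaks could be given. The window test, the outer and central parts, the width comparison, the clustering, the loss of strong peaks and the widest regions were chosen after the data were seen, as were the regions named for these.

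Planned results that needed a genome sequence or gene positions were left out. These were the share of peaks at promoters, the search for ONECUT and NK-2 motifs, and the gene lists. The gene table at hand is on the WBcel235 assembly, its coordinates were not used as evidence on regions of WS180, and a WS180 sequence and annotation were not used here. Regions are therefore given by position, without the genes in them.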

Results

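Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate the genomic binding sites of a GFP-tagged homeodomain transcription factor in third-stage (L3) larvae of Caenorhabditis elegans. The labels name the factor in 2 ways. Titles give CEH-28, an NK-2 class protein, whereas the strain (OP241) and genotype entries give a transgene of ceh-38, which encodes a ONECUT class protein. The tagged protein is therefore called the tagged factor here. The series held 2 anti-GFP ChIP samples and 2 input samples, the latter being total chromatin DNA saved before immunoprecipitation. A peak list was used for each ChIP replicate, together with a combined list. The replicate 1 list held 4082 peaks, the replicate 2 list 2867 and the combined list 6333. These covered 1.92, 1.76 and 3.22 Mb, which was 1.92%, 1.76% and 3.22% of the 100.1 Mb spanned by the peaks. The median peak width was 377 bp in replicate 1 and 478 bp in replicate 2 (428 bp ± 71.4, SD, n = 2), and 399 bp in the combined list. Read depth is unknown because the lists give q values and positions but no read counts. The labels do not say whether the replicates came from separate worm cultures, so differences between them may be technical.

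The first comparison asked how far the peaks of the 2 replicates coincided. Of the replicate 1 peaks, 2542 of 4082 (62.3%, exact 95% interval 60.8 to 63.8) overlapped a replicate 2 peak by at least 1 bp. Of the replicate 2 peaks, 2494 of 2867 (87.0%, 85.7 to 88.2) overlapped a replicate 1 peak. Circular shifts of the replicate 2 peaks within each chromosome gave 3.26% and 4.58% on average, so the observed shares were 19.1 and 19 times those of random positions. No shift reached the observed value (one-sided permutation test, 10000 shifts, p = 0.0001, the smallest they can give). Shared peaks lay close together, with centres a median of 43 bp apart, and 77.1% of the pairs had centres within 100 bp. Peaks of replicate 1 that were shared had a median −log10 q of 9.52 and a median width of 464 bp. The 1540 that were not shared had 4.43 and 261 bp.

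Sharing depended on the strength of the peak. In the 10% of replicate 1 peaks with the lowest q, 408 of 409 (99.8%) had a replicate 2 peak, against 86 of 408 (21.1%) in the 10% with the highest q. In replicate 2 the corresponding shares were 95.8% and 62.2%. The 12 peaks missing from the first of these replicate 2 classes included 10 of the 16 replicate 2 peaks with a −log10 q above 200. Across the 2542 shared peaks the −log10 q values of the replicates ranked alike, with a Spearman's rho of 0.77. Pearson's r was 0.87 on the log10 of the −log10 q values (two-sided permutation tests for both, 100000 resamples, p = 1e-05 each, the smallest they can give). This correlation is across peaks, which are not independent replicates. The q was lower in replicate 1 for 67.8% of the pairs, and the peak was wider in replicate 2 for 58.7%.

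**Figure D1:**
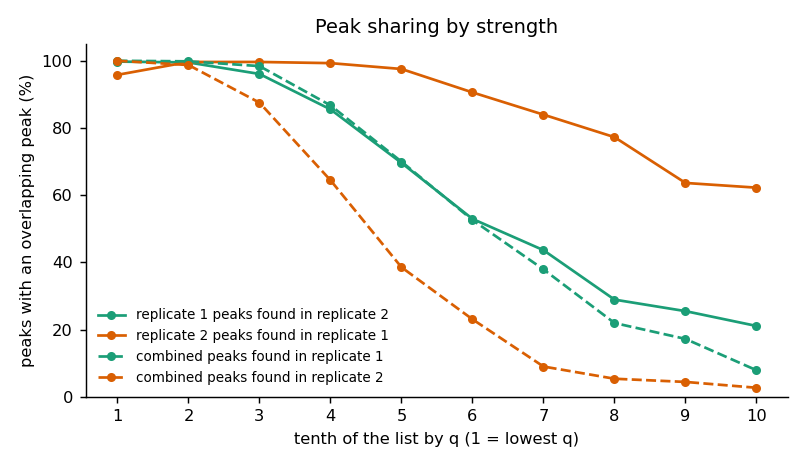
The share of peaks (%, y axis) with an overlapping peak in another list is plotted against the rank of the peak by q, in 10 classes from the lowest q to the highest (x axis). Solid lines compare the replicates with each other and dashed lines compare the combined list with each replicate. Sharing of replicate 1 peaks with replicate 2 went from 99.8% in the first class to 21.1% in the last.

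The combined list was compared with the lists of the single replicates. Of its 6333 peaks, 2430 (38.4%, exact 95% interval 37.2 to 39.6) overlapped peaks of both replicates. Another 1324 (20.9%) overlapped a replicate 1 peak only and 319 (5.04%) a replicate 2 peak only. The remaining 2260 (35.7%) overlapped neither list. Peaks with support in both replicates had a median −log10 q of 17.6 and a median width of 611 bp, against 4.35 and 276 bp for those with support in neither. In the other direction, 94.7% of replicate 1 peaks and 97.8% of replicate 2 peaks overlapped a combined peak.

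The replicate peaks without a combined peak included the most significant ones. Among replicate 1 peaks with a −log10 q above 200, 16 of 27 (59.3%) had no combined peak, against 1 of 162 (0.617%) between 50 and 200 (two-sided Fisher's exact test, p = 3.16e-15). In replicate 2 the counts were 15 of 16 (93.8%) and 13 of 137 (9.49%; Fisher's exact test, p = 2.46e-12), and 11 of those 13 were among the 22 between 150 and 200. The weakest peaks made up most of the other losses, since 195 of the 216 replicate 1 peaks without a combined peak had a −log10 q of at most 10. All 16 of these replicate 1 peaks overlapped a replicate 2 peak. On chromosome I, the region from 11383044 to 11387414 had a −log10 q of 296.7 in replicate 1 and 212.0 in replicate 2. On chromosome IV, the region from 2548403 to 2551918 had 296.7 and 202.1. On chromosome III, the region from 2111999 to 2113239 had 287.2 and 191.4. On chromosome II, the region from 3067067 to 3071800 had 314.5 and 161.9. Joining the peaks of both replicates with a −log10 q above 100 and no combined peak gave 27 regions with a median width of 2736 bp. Of these, 17 were present in both replicate lists and 10 in the replicate 2 list only. They lay on chromosomes I (11 regions), III (7), II (4), IV (4) and V (1). None of the 27 lay on X. A count of 0 allows a share of up to 11.1% (3 counts of 27, not a Clopper-Pearson limit). Of the 63 regions joined in the same way from replicate peaks that did have a combined peak, 14 lay on X (22.2%; two-sided Fisher's exact test, p = 0.0084). The regions with a combined peak were less significant, with a median −log10 q of 142.4 in the stronger replicate against 270.1 for the 27, so the comparison is not matched on strength.

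**Figure D2:**
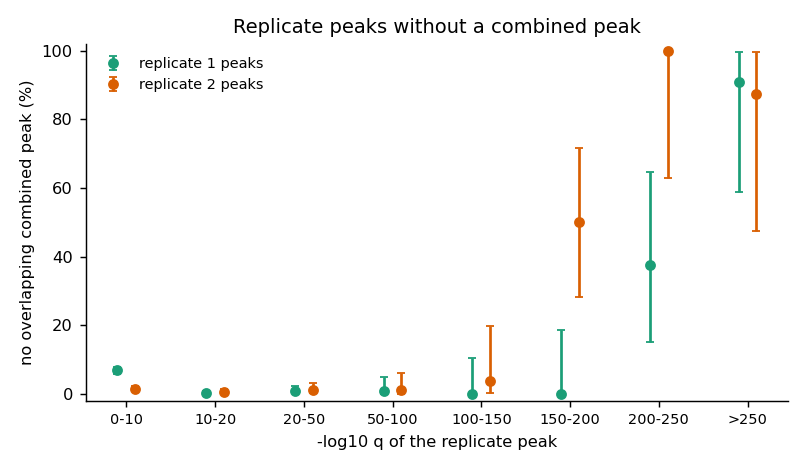
The share of replicate peaks (%, y axis) that overlapped no combined peak is plotted by the −log10 q of the replicate peak (x axis, unequal classes). Points are shares and bars are exact 95% binomial intervals. The share was 0 of 33 (interval up to 10.6%) for replicate 1 peaks with a −log10 q between 100 and 150, and 10 of 11 above 250.

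Among the combined peaks with support in both replicates, the 15 with the lowest q were 1288 to 2684 bp wide and had −log10 q values from 276.4 to 323.3. They lay on chromosomes X (5 peaks), I (4), IV (4) and III (2). The first was on X from 2996089 to 2997783, with a −log10 q of 323.3 in the combined list, which is the storage limit of double precision and so fixes neither its exact value nor its rank, 223.1 in replicate 1 and 170.6 in replicate 2. The next were on IV from 1434017 to 1435791 (319.9, 223.2 and 168.3 in the same order) and on IV from 976887 to 979570 (315.0, 202.4 and 154.9). The peak on X from 8035461 to 8037084 had 314.4, 288.1 and 264.8, and was the most significant peak of each replicate that also had a combined peak. This ranking leaves out the regions without a combined peak described above.

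The called peaks were spread unevenly over the 6 chromosomes. Chromosome III carried the highest density, with 1289 combined peaks or 93.6 per Mb, which was 1.48 times the even expectation (exact 95% interval 1.41 to 1.55). Chromosome I followed with 79.3 per Mb and a ratio of 1.25 (1.19 to 1.32). In the combined list density was lowest on X, at 47.8 per Mb and a ratio of 0.755 (0.708 to 0.804), followed by II at 50.1 per Mb (0.791) and V at 54.4 per Mb (0.860). Chromosome IV, at 63.4 per Mb, did not differ from the expectation (ratio 1.0, 0.949 to 1.06). The adjusted p-values from exact binomial tests were 3.87e-46 for III, 4.76e-16 for I, 2.91e-20 for X, 6.52e-13 for II, 6.57e-09 for V and 0.921 for IV (Benjamini-Hochberg over 6 chromosomes). Both replicates gave the same order at the top, with ratios for III of 1.67 in replicate 1 and 1.65 in replicate 2. The order at the bottom differed between lists. Replicate 1 gave 0.670 for X, 0.765 for II and 0.821 for V, whereas replicate 2 gave 0.823 for X, 0.700 for II and 0.806 for V. Combined peaks with support in both replicates had ratios of 0.785 for X, 0.691 for II and 0.787 for V.

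Because neighbouring peaks are not independent, densities were also compared over 97 windows of 1 Mb. Chromosome III windows held 94 ± 14 combined peaks (SD, n = 13 windows), against 58.6 ± 18.2 (n = 84) elsewhere. X windows held 48.2 ± 8.47 (n = 17), against 66.5 ± 22 (n = 80). Two-sided permutation tests with 100000 resamples gave adjusted p-values of 6e-05 for III, 0.0025 for I, 0.0025 for X, 0.0122 for II, 0.032 for V and 0.995 for IV. The tests treat windows as exchangeable, so likeness between adjacent windows would make these p-values too small. The densest window was on chromosome I from 1 to 2 Mb with 117 combined peaks, and 5 of the 6 densest were on III. The sparsest, on V from 17 to 18 Mb, held 28. Window counts of the replicates had a Spearman's rho of 0.89 across the 97 windows, which are not independent replicates.

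**Figure D3:**
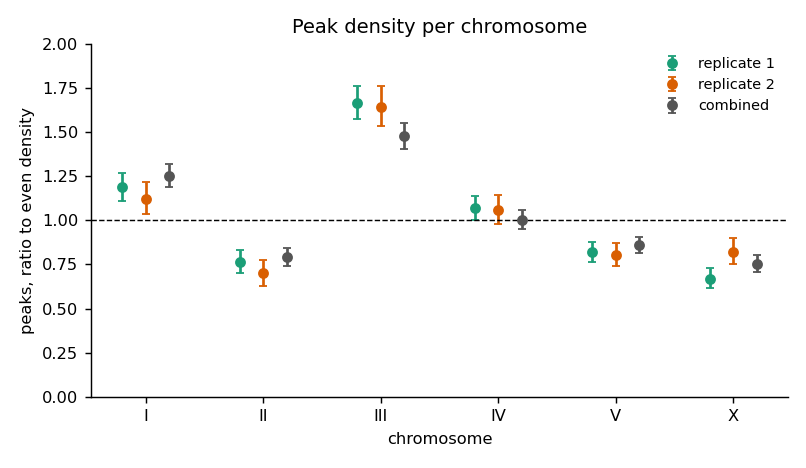
The number of peaks on each chromosome (x axis) is given as a ratio to an even density over the spanned length (y axis). Points are the replicate 1, replicate 2 and combined lists, bars are exact 95% binomial intervals, and the dashed line marks an even density. Chromosome III lay between 1.48 and 1.67 in the 3 lists and X between 0.670 and 0.823.

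**Figure D4:**
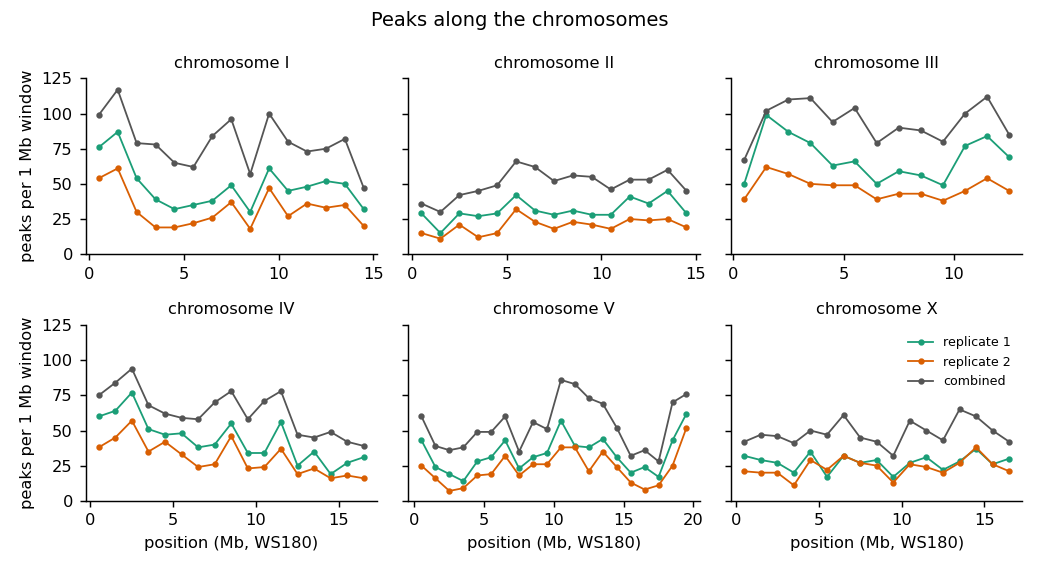
Peaks per 1 Mb window (y axis) are plotted along each chromosome (x axis, position in Mb on the WS180 build) for the replicate 1, replicate 2 and combined lists. Counts in the combined list ranged from 28 to 117 per window with a median of 60.

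Peaks on X were fewer but wider. Their median width was 497 bp in the combined list, against 384 bp on the autosomes, a mean difference of 0.43 ± 0.040 (SE) on the log2 scale or 1.34-fold. Peaks on III were narrower, at 346 bp against 408 bp elsewhere (−0.23 ± 0.038, SE). Both differences passed two-sided permutation tests over peaks (100000 resamples, p = 1e-05 each, the smallest they can give). The tests and SEs count each peak as independent although neighbouring peaks were clustered, so both are likely too small. No window or thinned version was run for the widths. X peaks were also wider in replicate 1 (450 against 365 bp, log2 difference 0.41) and replicate 2 (562 against 465 bp, 0.22). Peaks on III were narrower in replicate 1 (327 against 391 bp, −0.35) and replicate 2 (433 against 492.5 bp, −0.19). The size of both differences thus varied between the replicates. The combined list held 137 peaks narrower than 50 bp, down to 1 bp. These weigh on a mean of log2 widths, and no width comparison was run that set them aside by width. The covered length differed less than the peak number, at 2.99% of X and 4.27% of III. By covered length X was not the lowest, since V had 2.67% and II 2.94%.

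The strongest peaks lay towards the ends of the autosomes. C. elegans autosomes have gene-dense central regions and repeat-rich arms. Repeats and mappability were not measured and the input was not analysed here, so signal from repeats is not told apart from binding. Because arm boundaries on this build were not used here, the outer 25% at either end of the spanned length were compared with the central 50%. Among the 10% of autosomal peaks with the lowest q, 78.3% lay in the outer parts in replicate 1 (281 of 359, exact 95% interval 73.6 to 82.4), against 51% of the other peaks. The shares were 75.5% against 48.2% in replicate 2 and 68.8% against 46.8% in the combined list (two-sided Fisher's exact tests, adjusted p = 1.24e-23, 1.74e-16 and 1.16e-22 over the 3 lists). Each of the 5 autosomes showed this in every list, with adjusted p-values of at most 0.0158 over 18 tests by Fisher's exact test. Chromosome IV had the largest share in each list, at 85.3% in replicate 1, 80.8% in replicate 2 and 77.3% in the combined list. On X the shares were 62.5% against 52.6% in replicate 1 and 61.0% against 48.1% in replicate 2, and did not pass Fisher's exact test (adjusted p = 0.224 and 0.148). Whether X differed from the autosomes was not tested. All 27 strong regions without a combined peak lay in the outer parts, as did 48 of the 49 autosomal regions with a −log10 q above 100 that had one (98.0%; Fisher's exact test, p = 1), which were less significant (median 137.5 against 270.1).

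The position of peaks of any strength was less skewed. In the combined list the central 50% held 55.4% of the peaks on chromosome V (adjusted p = 0.00196, exact binomial test) and 54.7% on II (adjusted p = 0.0305). On I, III, IV and X the shares lay between 48% and 50.4% and did not pass. The call on II did not hold in replicate 1 (49.6%, adjusted p = 0.891) or in replicate 2 (52%, adjusted p = 0.686) by the exact binomial test. The share on I was 41.7% in replicate 1 and 42.3% in replicate 2, below 50% by the exact binomial test (adjusted p = 2.53e-05 and 0.00229). On III it was 41.5% and 45.6% (exact binomial test, adjusted p = 1.14e-06 and 0.0557). These tests count each peak as independent. Because neighbouring peaks were clustered, the p-values are likely too small, and no window or thinned version was run for these shares.

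Peaks were clustered along the chromosomes. In the combined list 26.3% of neighbouring peaks were separated by at most 2000 bp, against 11.9% in 1000 random placements, a ratio of 2.21 (one-sided permutation test, p = 0.001, the smallest they can give). The ratios were 2.63 in replicate 1 and 3.30 in replicate 2. One region stood apart by its width. It was on chromosome II from 6939193 to 6962185 in the combined list and was 22993 bp wide, 3.38 times the next widest peak. It was the widest peak in replicate 1 (22832 bp) and in replicate 2 (18969 bp) as well. Its −log10 q was modest at 20.2 in the combined list, 21.6 in replicate 1 and 10.5 in replicate 2.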

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

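Of the settings in this part, the shifts of 5 to 50 kb, the width limits, the added-back peaks, the peaks joined within 5 kb, the 1 Mb windows and those for peak position, width and clustering were chosen after the data were seen. Of 108 values recomputed under an alternative, 91 kept their direction and call. The share of replicate 1 peaks with a replicate 2 peak ranged from 48% (centres within 100 bp) to 77.9% (lists of equal length), and that of replicate 2 peaks from 68.3% to 90.3%, always above the shifted positions. Spearman's rho was 0.77 over all 2542 shared pairs. It was 0.84 over the 2259 pairs with a 50% reciprocal overlap. For the 1314 pairs in the 50% of lowest q of both lists it was 0.82. Both alternatives left out pairs that overlapped less or were weaker, so they do not show a range around the main value. The ratio for chromosome III ranged from 1.35 to 1.67 and that for X from 0.670 to 0.823, with every test past the threshold. Chromosome IV was called only with replicate 1 alone: its ratio was 1.06 without replicate 1 and 1.07 without replicate 2, adjusted p = 0.0475 by the exact binomial test. The median combined peak width was 571 bp in the 50% of peaks with the lowest q. The share of combined peaks with support in both replicates was 32.3% at a 50% reciprocal overlap and 39.7% in the 50% of each list with the lowest q. The central share on chromosome II was 50.0% in peaks of both replicates and ranged from 49.6% to 52% with either replicate left out; the cause was not tested. On chromosomes I and III it passed the threshold below 50% under 5 and 4 of 5 alternatives. Promoter, motif and gene list alternatives were not run, since those results need a WS180 genome or annotation. No paired analysis was possible because the input libraries, whose replicate numbers match those of the ChIP samples, were not analysed here. Depth is unknown, so whether an unshared peak was absent from the other replicate or missed there stays open.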

Other observations

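Of the tests in this part, those of the loss by q, of binding in 1 replicate, of the transgene, of central positions by support and of 1 peak per 100 kb were chosen after the results were seen. Peaks found in the combined list alone lay more centrally than those with support in both replicates on 2 chromosomes. The comparison was not matched on strength. Over all chromosomes the median −log10 q was 4.35 without support and 17.6 with support in both, and the strongest autosomal peaks lay towards the ends. Support and strength are therefore not told apart here. On chromosome I, 54.4% of the 487 peaks with support in neither replicate lay in the central 50%, against 42.0% of the 440 with support in both (two-sided Fisher's exact test, adjusted p = 0.00106 over 6 chromosomes). On III the shares were 55.2% of 382 and 43.3% of 543 (Fisher's exact test, adjusted p = 0.00118). On II, IV, V and X the differences did not pass Fisher's exact test (adjusted p from 0.0785 to 0.186). On V the share was lower in the peaks without support (53.6% against 58.9%). These tests also count clustered peaks as independent, so their p-values are likely too small. When only the strongest combined autosomal peak per 100 kb was kept, 75.3% of the strongest 10% lay in the outer parts, against 47.1% of the others (Fisher's exact test, p = 1.08e-06).

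Many of the most significant replicate peaks had no counterpart in the combined list. Binding in 1 replicate only is argued against for the lost replicate 1 peaks with a −log10 q above 200. Of these 16 peaks, 100% overlapped a replicate 2 peak. This explanation stays open for replicate 2, where 33.3% of the 15 lost peaks overlapped a replicate 1 peak. The replicate 1 list may itself lack strong peaks. It had no counterpart for 10 of the 16 replicate 2 peaks above 200. Between 50 and 200 it lacked 0 of 137 (Fisher's exact test, p = 5.58e-12). Among replicate 2 peaks above 50, the loss from replicate 1 was thus limited to the most significant ones. The 33.3% therefore does not by itself show binding in replicate 2 only. A candidate explanation is that peaks whose q was too small to store were left out of the lists; the loss of 59.3% of replicate 1 peaks above 200 prompted this explanation and does not test it. A line fitted to 161 weaker peaks put the expected combined q beyond the storage limit for 93.8% of the 16 lost peaks, but also for 6 of the 11 kept ones, so it separates them poorly. A set of masked regions stays open, since 89.1% of 46 weaker peaks within 10 kb of a lost one were kept (exact 95% interval 76.4 to 96.4) and a mask of single peaks would leave these in place.

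The region of 22993 bp on chromosome II was the widest peak of the combined list. Joining all combined peaks across gaps of up to 1000 bp gave no other region longer than 9873 bp. This argues against ordinary neighbouring peaks joined into 1 at gaps of that size. Wider gaps were not tried in this test, and a join peculiar to this region stays open. A candidate explanation is extra copies of the strain's transgene DNA, a long stretch around the tagged gene; the region had a −log10 q of 20.2, below all 25 other combined peaks over 3 kb (lowest 25.4, median 86.4), which does not measure copy number. In the WBcel235 gene table ceh-38, the gene in the strain's name, is on chromosome II and ceh-28, the gene in the titles, is on X, so the region may be the locus of ceh-38, in which case its signal need not be binding and the strain's name rather than the titles would give the tagged factor. This stays open, because the table's coordinates belong to another build and do not place the gene on WS180, and the copy number of the input was not analysed here.

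The density of peaks was uneven between chromosomes. With the lost replicate peaks added to the combined list the ratio of chromosome III was 1.51, but the 253 added peaks could not have brought it below 1.42 wherever they lay, so this test decides nothing on peaks left out of all lists. In the 50% of peaks with the lowest q it was 1.58, which argues against weak peaks near the threshold. A few dense windows are argued against by the medians of 94.0 peaks per 1 Mb window on III and 56.0 elsewhere. The permutation test over these windows gave p = 1e-05, treating adjacent windows as exchangeable. Mappability, base composition and gene density stay open, since none was measured here, and no biological explanation was tested because the samples share 1 strain and 1 stage.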
